A study of Oryza sativa Japonica Group with 238 samples.

How the data were processed

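Roots of rice (Oryza sativa cv. Nipponbare) were profiled in 238 libraries. RNA was measured in 187 libraries, of which 157 held TRAP RNA and 30 held TOTAL RNA. TRAP (translating ribosome affinity purification) pulls polysomes through a FLAG-tagged ribosomal protein L18, and the bound poly(A) RNA is then sequenced, per the labels' protocols. TOTAL RNA is the poly(A) RNA of the whole root. The 51 other libraries were ATAC-seq libraries, made with the Tn5 transposase from nuclei captured by an affinity tag on the nuclear envelope (INTACT). Each line carries its tag under another promoter, and the labels name the lines by that promoter. Greenhouse replicates are separate pots, since the labels state that the plants of a pot were combined as a single replicate. For field and plate groups the labels do not say what a replicate is. Every group had 3 replicates except plate-grown CMZ, which had 4.

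The RNA values are TPM of 28248 genes as the authors deposited them. Per the file headers, genes above a CPM minimum in at least 1 condition were kept, reads were quantile-normalized with limma voom, and TPM was then computed from the normalized reads. The deposited TPM columns sum to 999953 to 1000050, so they hold no sequencing depth, and the depth behind each RNA value is unknown. Quantile normalization gives each library nearly the same distribution of values, so the level of a gene that ranks first in a library is set by that shared distribution. The ATAC values are raw counts of reads per gene upstream region, as the authors deposited them, over 35678 regions, of which 143 were 0 in every library. The deposited counts per library summed to between 812498 and 17113727, with a median of 3099295. A total of counts in upstream regions leaves out the rest of each library. Per the submitters' processing notes, the tools were Bowtie2, TopHat2, HOMER and limma, and the genome build was IRGSP-1.0. Their versions and settings, and any shift of the ATAC reads for the Tn5 cut site, are not given in the sources used here. No reference genome was used here, and gene names are the descriptions paired with each gene identifier in the TPM data. The reference gene symbols matched 0 of the identifiers. A description written as "similar to" a protein names a resemblance. Close paralogs such as the dehydrins, metallothioneins and nicotianamine synthases can share reads, and how the counting divided such reads is not given in the sources used here, so their separate levels are uncertain. Whether the counting used strand is not given either.

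From the TPM values, limma 3.58.1 (R 4.3.3) was run on log2(TPM + 1) with eBayes and a mean trend, over genes with at least 1 TPM in at least 3 libraries of the fit. Fold changes are therefore on the log2(TPM + 1) scale, which understates the change of genes with low values. All environments of a line and RNA pool entered 1 fit and shared 1 estimate of the spread. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 fold change was at least 1 in size. Interactions of stress with line, and of submergence with line, were called on the adjusted p alone. Differences among lines were called on the moderated F test and a log2 difference of at least 1 from 35S in at least 1 line. Submergence was compared with the greenhouse control named II and the other stresses with control I. The labels do not tie control II to submergence, so this choice is an inference from where the control II libraries occur. Recovery groups were compared with the stress they followed. From the counts, edgeR 4.0.16 was run with TMM scaling, filterByExpr and the quasi-likelihood F test, at an adjusted p under 0.05 with no fold limit, and DESeq2 1.42.0 was run as an alternative. The R package data.table, version 1.17.8, read the files.

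The 21 gene lists were fixed before the data were examined, as words in gene descriptions and known identifiers, and their members were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over lists within a comparison. Word matching also took some genes of other function, such as fatty acid condensing enzymes under the word condensin and members of the wider zinc alcohol dehydrogenase superfamily. The comparisons, tests, thresholds, alternatives and the rule for naming genes were also set before the data were examined. The rule took the 10 largest rises and 10 largest falls in 35S TRAP RNA for deficit, waterlogging and submergence, 5 each way in other comparisons, and the 5 genes most above 35S in each line. It asked that the gene passed the test and that the higher group had a mean of at least 5 TPM, or 10 counts in the ATAC data. For RNA, but not for ATAC regions, it also asked that every treated library lay beyond every control library. Of 3 against 3 libraries without any effect, 10% of genes separate in this way. Called members of the gene lists, the genes whose promoters drive the tag and the RPL18 gene could be named as well, and genes without an informative name were named for at most 2 genes each way.

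The alternatives were a pseudocount of 0.1, no filter on low values, TPM rescaled by median-of-ratios size factors, a fit of only the groups compared, the replicate number as a block, control I for control II, DESeq2 and its size factors, the 500 genes with the smallest p, an estimated correlation, and each replicate left out in turn. A fit without greenhouse and field libraries above 1000 summed TPM of photosynthesis genes was added after the data were seen. For pairing, the deviations of same-numbered libraries from their group means were correlated, and numbers were taken to pair libraries where every correlation was over 0.1. This held for the deficit response of RSS1 (0.134 to 0.264), for the waterlogging response of TOTAL RNA (0.295 to 0.508) and of the 35S (0.476 to 0.62), RSS1 (0.194 to 0.305) and CASP (0.152 to 0.356) lines, for recovery from waterlogging (0.341 to 0.732), for recovery from submergence in 35S (0.106 to 0.254), and for TRAP against TOTAL RNA (0.194 to 0.417) and its interaction with waterlogging (0.137 to 0.62). The pairing comes from these data and not from the labels.

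The tests were checked on simulated data with 200 changed genes. In the deficit response of 35S TRAP RNA, over 26315 genes, limma recovered 84 of 100 genes changed by a log2 of 1.5 and 97 of 100 changed by 3, with 7 false calls. In the waterlogging response of CMZ, over 27630 genes, it recovered 30 and 77, with 8 false calls. For the deficit by line interaction, over 27909 genes, it recovered 8 and 63, with 4 false calls. In the ATAC deficit response of 35S, over 35390 regions, edgeR recovered 3 of 100 regions changed 1.5-fold and 41 of 100 changed 2-fold, with 1 false call. In CMZ, over 35318 regions, it recovered 1 and 13, with 2 false calls. ATAC libraries of recovery and field groups entered the fits of their line but were not compared here, and RNA groups outside the comparisons reported were examined only for 3 gene lists. No 2 libraries were identical, and the highest correlation between libraries was 0.9876 for TPM and 0.9732 for ATAC counts.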

Results

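The atlas covered rice roots in 62 RNA groups and 17 ATAC groups. Plants grew in a greenhouse with drained irrigation (control I and control II), without watering (water deficit), with standing water over the roots (waterlogging), or with the whole plant under water (submergence). Each stress was followed by a recovery of 1 day. Greenhouse roots were taken at 26 days, recovery roots at 27 days, paddy field roots at 49 days and roots from agar plates at 7 days. The 35S line, whose viral promoter is active in most cells, gave TOTAL and TRAP RNA, and 10 further lines, with other promoters, gave TRAP RNA. Levels are mean TPM ± SD of 3 libraries unless stated otherwise. The TPM table holds no sequencing depth, and the ATAC counts per library ranged from 812498 to 17113727.

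Genes whose promoters drive the tag were the first check of the lines. QHB (OS01G0854500), a homeobox gene known from the quiescent centre, stood at 174 ± 57.8 TPM in QHB TRAP RNA of control I, against 0.257 in 35S TRAP RNA (log2 difference 7.06, adjusted p = 4.98e-11). RSS1 (OS02G0606700), a gene of proliferating cells, reached 467 ± 194 TPM in its own line against 6.68 (5.94, adjusted p = 5.22e-09). LSI1 (OS02G0745100), the silicon influx transporter, reached 2474 ± 108 against 353.5 ± 84.5 (2.83, adjusted p = 2.05e-06). These 3 genes were also higher in their own lines in the field, at 69.95, 299.3 and 5457 TPM, and QHB and RSS1 on plates, at 604.9 and 919.1 TPM. In the field the SHR1 line held 18.2 ± 11.6 TPM of the GRAS gene OS07G0586900, listed for SHR1, against 3.93 ± 0.955 in 35S (1.78, adjusted p = 0.0291), but LSI1 held 105.8 ± 30.4. Beta-expansin 5 (OS04G0552200) stood at 2.16 ± 1.77 TPM in EXP5B and 0.138 in 35S, a difference that did not pass the test (adjusted p = 0.174). NRAMP5 (OS07G0257200) stood at 31.01 ± 15.7 TPM in its line in the field and 25.4 ± 6.86 in 35S, HMA5 (OS04G0556000) at 29.6 ± 21.1 and 27.0 ± 8.6, and neither SCARECROW gene of rice exceeded 5.16 TPM in the SCR line, whose promoter the labels name AtSCR. The transcript of the tagged protein itself, RPL18 (OS03G0341100), stood at 52520 ± 53200 TPM in 35S TRAP RNA, 47790 ± 60500 in LSI1, 17100 ± 577 in RSS1 and 4209 ± 1480 in QHB, but at 1350 ± 480 in CMZ, 1101 ± 310 in SCR and 1041 ± 782 in CASP, beside 920.0 ± 152 in TOTAL RNA. RPL18 ranked first in 14 libraries, at 109100 to 122900 TPM, and reached at most 32460 TPM at any other rank.

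**Figure D1:**
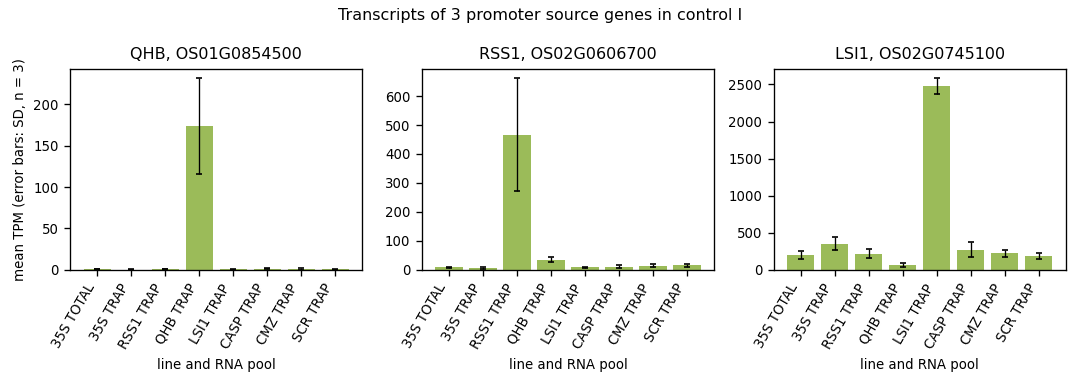
Mean TPM (bars, error bars SD, n = 3) of QHB, RSS1 and LSI1 in control I, by line and RNA pool. Each gene is highest in the line that carries its promoter, at 174, 467 and 2474 TPM.

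Water deficit raised transcripts of desiccation protectants to among the most abundant in the root. In 35S TRAP RNA the dehydrin RAB21 (OS11G0454300) rose from 52.5 ± 3.48 to 118700 ± 2670 TPM (log2 fold change 11.12, adjusted p = 1.56e-14), and it ranked first in 8 libraries, where its level of 111900 to 129700 TPM stands apart from at most 19030 TPM at other ranks. DHN1 (OS11G0451700) rose from 12.4 ± 2.94 to 5101 ± 1760 TPM, RAB16D (OS11G0453900) from 42.3 ± 13.9 to 18110 ± 11900, RAB16C (OS11G0454000) from 8.44 ± 1.66 to 2164 ± 642 and RAB16B (OS11G0454200) from 8.19 ± 0.65 to 2132 ± 762. Late embryogenesis abundant (LEA) genes OS03G0168100 and LEA1 (OS06G0110200) rose by log2 8.51 and 8.14, the cold-regulated Cor14b-like gene OS04G0610600 by 7.89, and an AWPM-19-like gene of abscisic acid responses (OS05G0381400) by 7.81. Nicotianamine synthases NAS2 (OS03G0307200) and NAS1 (OS03G0307300), which make the precursor of the phytosiderophores that carry iron into grass roots, fell from 394 ± 158 to 6.11 ± 2.76 TPM (-5.77, adjusted p = 1.35e-09) and from 328 ± 158 to 5.05 ± 2.42 TPM. Non-symbiotic hemoglobin 2 (OS03G0226200), an oxygen-binding protein linked to low-oxygen responses, fell from 635 ± 345 to 18.4 ± 9.02 TPM (-5.02, adjusted p = 2.91e-05). Further large falls were those of a Tfm5-like gene (OS10G0552600, -5.39), a lipid transfer protein (OS07G0287400, -5.15), a receptor-like protein of iron acquisition (OS04G0659300, -4.99), a haem peroxidase (OS07G0104500, -4.87), a metal transport protein (OS03G0667300, -4.80) and a B12D-like protein (OS07G0604600, -4.62). In all, limma called 3790 of 26315 genes, 1586 higher and 2204 lower, in 35S TRAP RNA, and 5690 of 26506 genes, 2803 higher and 2887 lower, in TOTAL RNA.

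By group, 21 of the 27 measured genes of the LEA and dehydrins list rose in 35S TRAP RNA and none fell (median log2 6.08, adjusted p = 2.4e-32). Of the 16 genes of ABA metabolism and signalling, 11 rose and 1 fell, with 12 and 1 adjusted over the list alone (median 2.18, adjusted p = 1.99e-08). They included a bZIP activator of ABA signalling (OS06G0211200), which rose from 11.2 ± 1.7 to 172.5 ± 13.8 TPM, protein phosphatases of type 2C (OS03G0268600, 3.31, and OS09G0325700, 3.07), and viviparous-14 (OS12G0617400, 2.68, adjusted p = 0.00221), a gene of ABA synthesis. Of the 14 genes of iron acquisition, 8 fell and 1 rose (median -1.39, adjusted p = 0.000384, and adjusted p = 0.187 with an estimated correlation). A nicotianamine aminotransferase (OS02G0306401) fell from 129.7 ± 57.6 to 5.46 ± 1.69 TPM and the iron-phytosiderophore transporter (OS02G0650300) by 1.86 on the log2 scale. Among the 5 hypoxia regulators, ethylene response factors of low-oxygen signalling, 3 fell, or 4 adjusted over the list alone (median -1.68, adjusted p = 0.02, and 0.0908 with an estimated correlation). OS03G0341000 fell from 48.2 ± 25.5 to 5.18 ± 1.51 TPM. Of 38 expansins, which loosen cell walls, 9 fell and 2 rose (10 lower adjusted over the list alone, adjusted p = 0.02), with an expansin-A9-like gene (OS01G0249100) at 5.52 ± 3.89 against 71.7 ± 6.72 TPM. Of 17 aquaporins 5 fell (adjusted p = 0.0334), among them the tonoplast protein TIP2 (OS02G0658100), from 125 ± 34.1 to 10.1 ± 8.65 TPM. Of 28 nitrate, ammonium and phosphate transporters 8 fell and 2 rose (adjusted p = 0.0282). From expansins on, the adjusted p with an estimated correlation was 0.487, 0.6 and 0.6. The 28 genes of anaerobic fermentation did not move together as a list. A sucrose synthase (OS03G0340500) rose from 17.8 ± 5.33 to 321.2 ± 5.11 TPM, while hemoglobin 1 (OS03G0233900) fell by 4.05 on the log2 scale and a lactate dehydrogenase (OS06G0104900) by 2.56.

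**Figure D2:**
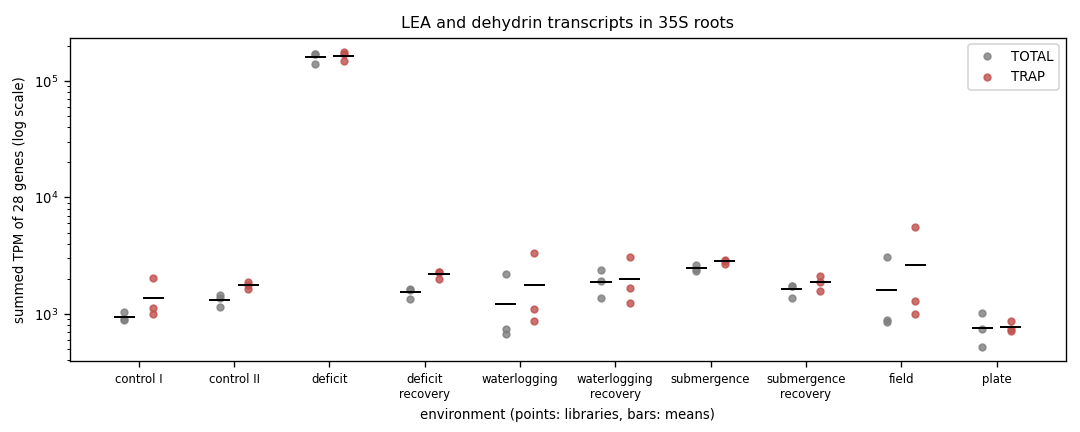
Summed TPM (log scale) of the 28 genes of the LEA and dehydrins list in each library of the 35S line (points) with group means (bars), by environment and RNA pool. The deficit libraries lie between 141100 and 176400 TPM, above every other library, the highest of which holds 5555 TPM.

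TOTAL RNA added falls among genes of cell division. Of 76 genes of DNA replication and histones, 44 fell and 1 rose (median -1.08, adjusted p = 1.11e-13, and 0.0233 with an estimated correlation). Of 24 genes of the mitotic cell cycle 10 fell (median -0.888, adjusted p = 3.48e-06, and 0.0498 with an estimated correlation). A histone H2A gene (OS01G0502700) fell from 84.9 ± 9.56 to 14.1 ± 3.69 TPM and cyclin-B1-5 (OS05G0493500), a mitotic cyclin, by 1.97 on the log2 scale, while a histone H2B gene (OS09G0570850) rose from 0.424 ± 0.268 to 82.1 ± 50.6 TPM. Of 44 expansins 26 fell and 1 rose (median -1.69, adjusted p = 1.28e-13). Of 19 aquaporins 10 fell and 1 rose (adjusted p = 0.000856). Of 14 genes of iron acquisition 10 fell and 2 rose (adjusted p = 2.37e-05). Of the heat shock proteins 21 rose and 4 fell (adjusted p = 0.00634). Of the 160 cytosolic ribosomal proteins 7 fell (median -0.519, adjusted p = 1.01e-11). Of 31 genes of anaerobic fermentation 15 fell and 6 rose (adjusted p = 0.00391). Of 55 genes of phenylpropanoid and lignin synthesis 13 fell and 6 rose (14 lower adjusted over the list alone, adjusted p = 0.0126). From expansins on, the adjusted p with an estimated correlation was 0.0291, 0.277, 0.0778, 0.289, 0.283, 0.283 and 0.283 in that order. The LEA and dehydrins list had 22 of 28 genes higher (median 6.75), RAB21 rose by 11.46, hemoglobin 2 fell from 1809 ± 458 to 8.89 ± 4.89 TPM, and NAS2 from 1826 ± 923 to 10.0 ± 6.86.

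**Figure D3:**
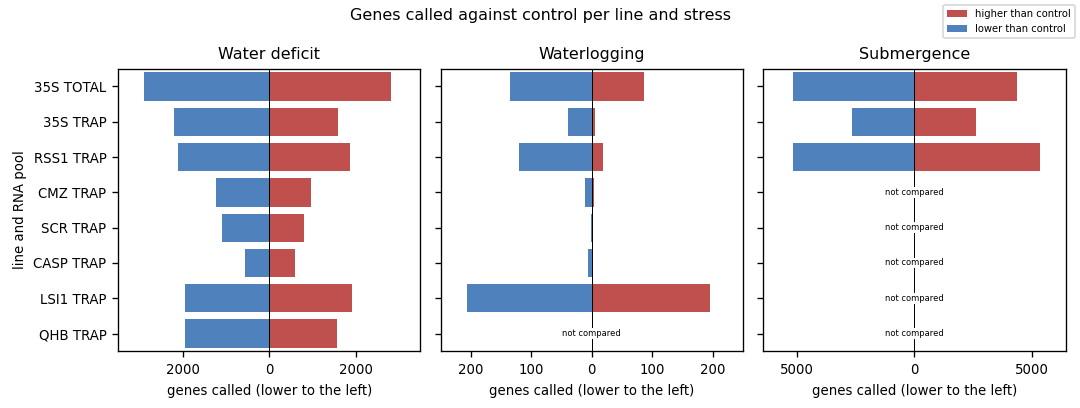
Number of genes called higher (right) and lower (left) than control by limma, per stress, line and RNA pool, with a different scale in each panel. Deficit called 3790 genes, waterlogging 45 and submergence 5289 in 35S TRAP RNA.

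The other lines shared the rise of protectants. Of the LEA and dehydrins list, RSS1 had 21 of 28 genes higher (22 adjusted over the list alone), CMZ 23 of 28, SCR 20 with 1 lower, CASP 21 with 1 lower, LSI1 21 of 27 and QHB 18 of 27 (20 adjusted over the list alone), each with an adjusted p of 0.0213 or less with an estimated correlation. Genes of ABA metabolism and signalling rose in RSS1 (12 of 16), CMZ (10), SCR (6 of 15), CASP (8), LSI1 (12) and QHB (9), and these calls held with an estimated correlation, at adjusted p of 0.0454 or less. The list of iron acquisition fell in RSS1 (9 of 15), CMZ (6), SCR (8) and CASP (7), and in LSI1 (8, adjusted p = 0.000101, and 0.0626 with an estimated correlation). In CASP, NAS2 fell from 393.9 ± 71.7 to 10.7 ± 1.46 TPM. Expansins fell in RSS1 (26 of 46, with 2 higher), CMZ (15), SCR (12), CASP (9) and QHB (15 of 42). Genes of the mitotic cell cycle fell in CMZ (5) and QHB (10), at adjusted p of 0.00864 and 0.0454 with an estimated correlation. RAB21 rose to 15590 ± 1610 TPM in RSS1 and to 89060 ± 67100 in LSI1. An EC metallothionein (OS10G0542100) led the rises in SCR (8.41) and was among those of CMZ (7.96). A seed maturation protein (OS06G0341300) was among the leading rises in RSS1 (8.27), CMZ (8.24) and CASP (7.26). Phosphoenolpyruvate carboxykinase (OS10G0204400), an enzyme of gluconeogenesis, fell by 5.22 in CMZ, 5.61 in SCR and 5.30 in CASP. The root-specific RCc3 gene OS04G0554600 fell from 498.7 ± 207 to 6.99 ± 7.96 TPM in RSS1. In LSI1, lactate dehydrogenase (OS06G0104900) fell from 1009 ± 359 to 7.92 ± 3.05 TPM, a B12D-like gene (OS07G0604700) from 489.7 ± 80.1 to 2.15 ± 2.08, and all 3 genes of secondary wall cellulose rose (median 1.93, adjusted p = 0.00349, and 0.25 with an estimated correlation). In QHB, 22 of 54 genes of phenylpropanoid and lignin synthesis fell and 3 rose (26 lower adjusted over the list alone, median -1.20, adjusted p = 0.00365 with an estimated correlation). Also in QHB the root-specific RCc2 gene (OS10G0349300) fell from 179 ± 76 to 1.69 ± 1.39 TPM, and 28 of 77 genes of DNA replication and histones fell (adjusted p = 3.75e-09, and 0.175 with an estimated correlation). In SCR the photosynthesis list had a median of 1.1 with 0 genes called by limma (adjusted p = 0.00896, and 0.7 with an estimated correlation), and deficit replicate 3 held 2229 summed TPM against at most 289.1 in the other 2.

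Called genes numbered 3977 in RSS1, 2178 in CMZ, 1882 in SCR, 1153 in CASP, 3852 in LSI1 and 3506 in QHB. Single libraries moved 2 of these counts. SCR gave 1147, 1194 or 1182 genes without control I replicate 1, 2 or 3 and 998 without deficit replicate 2. CASP gave 585 genes higher and 568 lower, and 753 in all without control I replicate 2. After rescaling it gave 761 higher and 467 lower, with the median of all genes at -0.14 before and -0.0023 after. The size of the response itself differed between lines for 1446 genes (moderated F test, 8 of 100 genes changed by log2 1.5 recovered in simulation). The count was 2315 with the replicate number as a block, and 942, 953 or 941 without LSI1 control I replicate 1, control I replicate 2 or deficit replicate 1. Against 35S, the secondary wall cellulose list responded more in LSI1 (3 of 3 genes, median 2.27, adjusted p = 0.0327 with an estimated correlation) and expansins responded more negatively in RSS1 (11 of 46, 17 adjusted over the list alone, median -0.41, adjusted p = 0.0161 with an estimated correlation).

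Waterlogging changed fewer genes than deficit in each of the 7 RNA sets that had both, and outside LSI1 most of those called were lower. In 35S TRAP RNA the ACC oxidase OS11G0186900, which makes ethylene, fell from 73.7 ± 15.4 to 3.86 ± 1.08 TPM (-3.94, adjusted p = 2.62e-07), and in LSI1 from 164.1 ± 32.1 to 9.72 ± 1.79. An IAA-amino acid hydrolase (OS03G0836800), which frees auxin from conjugates, fell from 30.2 ± 2.95 to 1.51 ± 0.851 TPM. A glycosyl hydrolase of family 18 (OS05G0247100) fell in 35S TRAP RNA (-3.34), TOTAL RNA (-3.26), RSS1 (-3.53), CMZ (-3.53) and SCR (-2.69, adjusted p = 0.0233), where it was the 1 gene called. Other falls in 35S TRAP RNA were those of glutathione S-transferase GST28 (OS01G0949800, -2.77), an allantoin permease (OS12G0503000, -2.69), a germin-like protein (OS08G0189100, -2.40) and the cytochrome P450 CYP71Y10 (OS06G0641500, -2.38). Among the 6 rises was an MtN3-type sugar transporter (OS01G0606000), from 2.48 ± 1.43 to 11.7 ± 3.08 TPM (adjusted p = 0.0032). The calls of a DOMON-domain gene (OS01G0893700, 1.98) and an NB-ARC gene (OS10G0161400, 1.04) were lost with a pseudocount of 0.1. In TOTAL RNA, phenylalanine ammonia-lyase (OS02G0626100), the entry enzyme of phenylpropanoid synthesis, rose from 3562 ± 858 to 35030 ± 558 TPM (adjusted p = 0.00387), and it ranked first in 5 libraries. The phenylpropanoid and lignin list, which holds it, summed to 38990 ± 858 TPM there against 6605 ± 1070 in control I, but also to 40530 ± 1730 in the unstressed control II and 40530 ± 1790 in the field. A dirigent-like gene (OS10G0334500) rose from 82.2 ± 39.5 to 571.7 ± 111 TPM, and the proteinase inhibitor MPI (OS12G0548700) fell by 3.30 on the log2 scale. In RSS1, hemoglobin 1 fell from 1462 ± 478 to 126.3 ± 39.5 TPM and phosphoenolpyruvate carboxykinase fell by 3.37. In CASP, BURP11 (OS06G0302000) fell from 47.8 ± 9.74 to 3.05 ± 1.19 TPM. In CMZ an ankyrin-repeat gene (OS06G0128700) rose from 12.9 ± 1.54 to 95.4 ± 23.5 TPM.

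With all libraries LSI1 had the most genes called under waterlogging, 196 higher and 207 lower, and 672 higher and 311 lower in a fit of only the groups compared. Without any 1 of its libraries it had 105 to 153, and TOTAL RNA 126 to 249. A bHLH factor (OS03G0741100) rose from 14.9 ± 8.17 to 293.2 ± 152 TPM (4.23, adjusted p = 0.0382) and DREB1C (OS06G0127100) from 21.2 ± 10.8 to 322.8 ± 50.5 (3.96, adjusted p = 0.0266). Of its 16 genes of ABA metabolism and signalling 3 rose, 5 adjusted over the list alone (median 0.35, adjusted p = 0.0499 with an estimated correlation). These were ABA 8'-hydroxylase 1 (OS02G0703600, 3.25), which breaks ABA down, a protein phosphatase 2C (OS03G0268600, 2.08) and a NAC gene (OS03G0815100), from 150.8 ± 12.5 to 530 ± 32.4 TPM. Of the genes lower in 35S TRAP RNA, 17 were also lower in LSI1, against 0.306 for independent lists (Fisher's exact test, adjusted p = 1.07e-25).

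The list of iron acquisition passed the test in 5 of the 7 RNA sets under waterlogging. Its median was -0.78 in TOTAL RNA (0 of 14 genes called by limma over all genes) and -0.91 in CMZ (0 of 15 called). Each had 3 lower adjusted over the list alone (adjusted p = 0.0199 and 0.0129 with an estimated correlation). The median was -0.66 in 35S TRAP RNA (0 called, 4 lower adjusted over the list alone, adjusted p = 6.26e-06, and 0.17 with an estimated correlation). In SCR, 3 were lower adjusted over the list alone (adjusted p = 1.26e-06, and 0.094 with an estimated correlation), and in RSS1 the median was -0.50 (adjusted p = 0.00493, and 0.213 with an estimated correlation) while the sum was 6197 ± 5320 against 6181 ± 1820 TPM. CASP (-0.17) and LSI1 (0.15) did not pass. The list summed to 1044 ± 685 TPM in waterlogged TOTAL RNA and 3525 in control I, but to 1094 ± 322 in the unstressed control II. In 35S TRAP RNA these sums were 733.6, 1397 and 497.8. In 35S TRAP RNA the hypoxia regulators had a median of 0.41 with 0 of 5 genes called (adjusted p = 0.023, and 0.17 with an estimated correlation). They did not pass in the other sets, RSS1 and SCR having negative medians, although in LSI1 their sum was 1766 ± 139 against 822.2 ± 83.9 TPM (adjusted p = 0.116). In 35S TRAP RNA suberin and Casparian strip genes had 0.35 with 0 of 11 called (adjusted p = 0.003, and 0.25 with an estimated correlation). There aquaporins had -0.38 (adjusted p = 0.00174) and cytosolic ribosomal proteins -0.32 (adjusted p = 6.49e-18). Each had 0 called and an adjusted p of 0.433 with an estimated correlation. The list of anaerobic fermentation had a positive median of 0.02 in TOTAL RNA while its test pointed down (adjusted p = 0.0132, and 0.459 with an estimated correlation). Transcripts of photosynthesis moved with single libraries. The photosynthesis list was higher in RSS1 (median 1.14, 0 of 42 genes called, adjusted p = 1.97e-10) and SCR (0.92, adjusted p = 0.00144). It was lower in CASP (-0.70, adjusted p = 0.0165). With an estimated correlation these were 0.214, 0.737 and 0.884. RSS1 waterlogging replicate 1 held 1898 summed TPM of these genes, SCR waterlogging replicate 3 held 5583, CMZ waterlogging replicate 3 held 3871 and CASP control I replicate 3 held 3731.

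**Figure D4:**
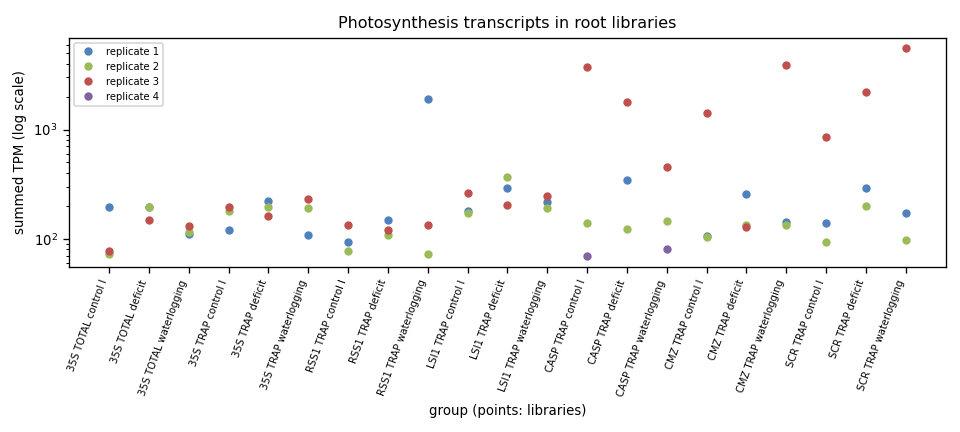
Summed TPM (log scale) of the photosynthesis list in each library (points, coloured by replicate number) of control I, deficit and waterlogging. Replicate 3 holds 1427 TPM in CMZ control I, 2229 in SCR deficit and 5583 in SCR waterlogging.

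The number of genes called under waterlogging rested on few libraries. TOTAL RNA gave 222 genes, 87 higher and 135 lower, and 46 higher and 191 lower after rescaling, which moved the median of all genes from 0.18 to 0.03. It gave 147 genes without control I replicate 3 and 126 without waterlogging replicate 3. TRAP RNA of 35S gave 45 genes, 6 higher and 39 lower, with 21 or 16 without control I replicate 1 or 3 and 23 without waterlogging replicate 3. RSS1 gave 139 genes, 18 higher and 121 lower. Without RSS1 control I replicate 1 or 3 it gave 59 or 80, without waterlogging replicate 1, 2 or 3 it gave 70, 66 or 82, and replicate 1 was also the library rich in photosynthesis transcripts. CMZ gave 14 genes, 3 higher and 11 lower, with 6, 5 or 2 without control I replicate 1, 2 or 3 and 9 without waterlogging replicate 2. SCR gave 1 gene, with 1287 at an unadjusted p under 0.05. It gave 0 without control I replicate 1 or 2, again by limma, 2, 12 or 10 without waterlogging replicate 1, 2 or 3, and 13 without its libraries rich in photosynthesis transcripts. CASP gave 7 lower genes, 23 with the replicate number as a block, 4 after rescaling, 2 without control I replicate 2 or waterlogging replicate 2, and 3 without waterlogging replicate 4. LSI1 gave 403 genes, with 130, 105 or 107 without control I replicate 1, 2 or 3 and 112, 153 or 133 without waterlogging replicate 1, 2 or 3. In a fit of only the groups compared, TOTAL, 35S, RSS1 and CMZ gave 111, 3, 63 and 6 genes. The response differed between lines for 21 genes, 118 with the replicate number as a block and 32 after rescaling. Leaving out single libraries moved that number by over 1.5 times in 18 cases. For control I libraries it was 34 or 44 without CASP replicate 2 or 4, 8 or 10 without CMZ replicate 1 or 3, 10, 2 or 2 without LSI1 replicate 1, 2 or 3, 11 without RSS1 replicate 3, and 11 or 9 without SCR replicate 1 or 2. For waterlogging libraries it was 9 without CMZ replicate 2, 3, 9 or 7 without LSI1 replicate 1, 2 or 3, 13, 9 or 11 without RSS1 replicate 1, 2 or 3, and 71 without SCR replicate 2.

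Submergence changed more genes than waterlogging in each of the 3 RNA sets that had both. In 35S TRAP RNA, DIN1 (OS12G0428000), a senescence-associated gene known from dark and sugar starvation, rose from 9.86 ± 2.07 to 883.8 ± 153 TPM (6.35, adjusted p = 4.73e-10), and a class III chitinase (OS11G0701500) from 3.21 ± 2.45 to 204.6 ± 80.4. The receptor-like gene OS04G0659300 rose from 660.8 ± 404 to 68950 ± 39900 TPM, and it ranked first in 2 libraries. A polygalacturonase β chain (OS10G0409400, 5.64), glutaredoxin-S8 (OS05G0149950, 5.32), a dihydroflavonol reductase-like gene (OS03G0184550, 5.28), a peroxidase (OS04G0688300, 5.23) and an allantoin permease (OS12G0503000, from 2.42 ± 1.41 to 113.8 ± 36.8 TPM) rose as well. The metallothionein RicMT (OS01G0974200), a metal-binding protein, fell from 89440 ± 66400 to 380.4 ± 88.4 TPM, and it ranked first in 10 libraries. A GDA1/CD39 nucleoside phosphatase (OS11G0126800) fell from 420.2 ± 20.4 to 6.59 ± 4.4 TPM, a physical impedance induced protein (OS03G0103200) from 4205 ± 902 to 98.3 ± 57.9, a SWEET sugar transporter (OS05G0214300) from 92.3 ± 43.4 to 1.29 ± 1.26 and a laccase (OS03G0273200), an enzyme of lignin polymerization, from 42.4 ± 18.1 to 0.333 ± 0.216. The probenazole-induced PBZ1 gene (OS12G0555100, -5.54), a safener binding protein (OS11G0306400, -5.43) and BURP-domain genes (OS05G0217700, -5.15, and OS06G0302000, -4.97) also fell. In TOTAL RNA DIN1 rose by 7.38, the IAA-amino acid hydrolase OS03G0836800 fell from 171.8 ± 39.1 to 0.447 TPM and TIP2 from 358.1 ± 55.1 to 3.72 ± 0.747. In RSS1 DIN1 rose by 7.16, a MYB-related gene (OS01G0975300) from 170.8 ± 121 to 10460 ± 6220 TPM, and the hydrolase OS03G0836800 fell by 7.07 on the log2 scale. Called genes numbered 5289 (2626 higher, 2663 lower) in 35S TRAP RNA, 9510 (4345 and 5165) in TOTAL RNA and 10495 (5317 and 5178) in RSS1, where the median of all genes lay at 0.11 and at 0.05 after rescaling.

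Under submergence several lists of growth and wall synthesis held more falls than rises, above all in TOTAL RNA and RSS1. Of 160 cytosolic ribosomal proteins, 114 fell and 3 rose in TOTAL RNA (median -1.47, adjusted p = 1.18e-22, and 0.0982 with an estimated correlation) and 108 fell and 4 rose in RSS1 (median -1.35, adjusted p = 3.26e-21, and 0.176 with an estimated correlation). In TRAP RNA of 35S 2 rose and the median was -0.28 (adjusted p = 0.024, and 0.919 with an estimated correlation). Genes of DNA replication and histones fell in TOTAL RNA (45 of 76, median -1.30, adjusted p = 9.77e-10) and RSS1 (47 of 77). Genes of the mitotic cell cycle fell in TOTAL RNA (17 of 24, with 2 higher, adjusted p = 1.06e-06) and RSS1 (15 of 24, with 3 higher). With an estimated correlation both had an adjusted p of 0.0526 in TOTAL RNA, and 0.0259 and 0.03 in RSS1. Of the mitotic genes 5 of 24 fell and 1 rose in 35S TRAP RNA (adjusted p = 0.0453, 0.533 with an estimated correlation and 0.0508 after rescaling). The list of expansins fell in TOTAL RNA (30 of 44, median -2.46, adjusted p = 8.13e-11, and 0.0526 with an estimated correlation) and RSS1 (31 of 46, with 4 higher, adjusted p = 0.00954 with an estimated correlation). All 3 genes of secondary wall cellulose fell in 35S TRAP RNA (median -4.83, adjusted p = 7.9e-07) and in TOTAL RNA (median -5.31, adjusted p = 0.00049), at 0.0602 and 0.0982 with an estimated correlation. The cellulose synthase OS10G0467800 fell from 83.6 ± 37.6 to 2.21 ± 0.624 TPM in 35S TRAP RNA. Genes of phenylpropanoid and lignin synthesis fell in RSS1 (33 of 55, with 3 higher), in 35S TRAP RNA (18 of 53, with 1 higher, or 4 higher adjusted over the list alone, adjusted p = 0.00027) and in TOTAL RNA (25 of 55, with 4 higher, adjusted p = 0.000103). With an estimated correlation the adjusted p was 0.0181, 0.112 and 0.0982 in that order. A 4CL-like gene (OS02G0177600) fell from 514.6 ± 50 to 63.1 ± 10.6 TPM in 35S TRAP RNA. Genes of suberin and Casparian strip synthesis fell in RSS1 (6 of 12, with 1 higher, adjusted p = 0.0043, and 0.151 with an estimated correlation).

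The hypoxia regulators rose in RSS1 (5 of 5 genes, median 2.03, adjusted p = 0.0259 with an estimated correlation) and TOTAL RNA (4 of 5, median 2.23, adjusted p = 0.0125, and 0.0526 with an estimated correlation). Of the 5, 3 rose in 35S TRAP RNA, or 4 adjusted over the list alone (median 2.04, adjusted p = 0.0453, 0.226 with an estimated correlation and 0.0545 with a pseudocount of 0.1). OS09G0287000, an ethylene response factor, rose from 7.12 ± 1.2 to 62.1 ± 22.2 TPM. Fermentation genes went both ways in 35S TRAP RNA. An alcohol dehydrogenase (OS03G0189400) rose by 1.45, and a pyruvate decarboxylase (OS03G0293500) fell from 145.7 ± 19.4 to 35.2 ± 6.6 TPM. The list of aquaporins fell in RSS1 (15 of 20, adjusted p = 1.53e-06) and TOTAL RNA (13 of 19, adjusted p = 0.000826). It fell in 35S TRAP RNA (8 of 17, or 10 adjusted over the list alone, adjusted p = 0.00526). These were 0.062, 0.245 and 0.519 with an estimated correlation. The plasma membrane protein OS02G0823100 stood at 44.5 ± 4.97 against 437 ± 155 TPM in 35S TRAP RNA. Of 76 pathogenesis-related genes 27 rose and 5 fell in 35S TRAP RNA (29 higher adjusted over the list alone, adjusted p = 0.024, and 0.519 with an estimated correlation). Photosynthesis transcripts were higher in submerged roots. Their sum was 679 ± 243 TPM against 166.1 ± 19.3 in 35S TRAP RNA, 410.8 ± 74.4 against 89.8 ± 27.2 in TOTAL RNA and 604.6 ± 327 against 110.1 ± 55 in RSS1. In all 28 of 44 genes of the photosynthesis list rose and 1 fell in 35S TRAP RNA (median 1.36, adjusted p = 9.79e-08, and 0.368 with an estimated correlation).

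Of the genes that rose in 35S TRAP RNA, 1732 also rose in RSS1, against 500.8 for independent lists, and 1834 fell in both against 505 (Fisher's exact test, odds ratios 12.4 and 14.5). The response itself differed between RSS1 and 35S for 3663 genes, 1633 more positive and 2030 more negative in RSS1. RicMT responded less negatively in RSS1 (interaction 6.47, adjusted p = 0.00297), where it stood at 526.9 ± 313 TPM under submergence and 801.1 ± 60.7 in control II. Cinnamyl alcohol dehydrogenase (OS09G0399800), an enzyme of lignin synthesis, responded more negatively (-5.64), at 4.08 ± 3.64 against 135.5 ± 24.1 TPM in RSS1. Of 44 expansins 23 responded more negatively and 1 more positively (27 and 3 adjusted over the list alone). Of 76 genes of DNA replication and histones 36 responded more negatively (46 with 1 more positive adjusted over the list alone). Of 160 cytosolic ribosomal proteins 62 responded more negatively, with 1 more positive (median -1.02, adjusted p = 1.26e-19). With an estimated correlation the adjusted p was 0.00555, 0.0074 and 0.27 in that order. In these lists TOTAL RNA differed from 35S TRAP RNA in the same direction, so this is not particular to RSS1. Tag enrichment was not separated from it. The line difference covered 2113 genes with control I in place of control II. It covered 2207, 2376 or 2304 without 35S control II replicate 1, 2 or 3, 2361 or 2237 without 35S submergence replicate 1 or 2, and 1944 without RSS1 control II replicate 2.

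One day of recovery from deficit returned the protectants most of the way. RAB21 in 35S TRAP RNA fell from 118700 ± 2670 to 450.5 ± 52.6 TPM and DHN1 fell by 6.74, and 22 of 27 genes of the LEA and dehydrins list fell with 1 higher (median -5.53, adjusted p = 0.000208 with an estimated correlation). Of 16 genes of ABA metabolism and signalling 11 fell and 1 rose (13 lower adjusted over the list alone, adjusted p = 0.0269 with an estimated correlation). A haem peroxidase (OS07G0104500) rose from 2.38 ± 1.11 to 237.1 ± 105 TPM and hemoglobin 2 by 5.47. RPL18 rose from 1655 ± 340 to 79860 ± 56500 TPM, which includes the tagged transcript. Of 14 genes of iron acquisition 5 rose and 1 fell (adjusted p = 0.0162). Of 28 nitrate, ammonium and phosphate transporters 7 rose and 2 fell (adjusted p = 0.00371). Of 5 hypoxia regulators 3 rose (adjusted p = 0.016). Of 38 expansins 9 rose and 2 fell (adjusted p = 0.016). From iron acquisition on, these were 0.42, 0.42, 0.0981 and 0.42 with an estimated correlation. In all 2049 genes rose and 1622 fell.

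After waterlogging, 7 genes rose and 3 fell in the recovery of 35S TRAP RNA. The ACC oxidase OS11G0186900 rose from 3.86 ± 1.08 to 26.2 ± 4.43 TPM (2.49, adjusted p = 0.00167) and a proline-rich protein (OS07G0418600) by 3.08. The calls of RAB16C (2.43), a pathogen-related protein (OS01G0731100, 2.26) and a 1-Cys peroxiredoxin (OS07G0638400, -2.03) were lost with the replicate number as a block and with a pseudocount of 0.1. The LEA and dehydrins list had a median of 0.54 (1 of 27 higher, 9 adjusted over the list alone, adjusted p = 0.0254 with an estimated correlation), and secondary wall cellulose genes one of 1.27 (0 called, 2 higher adjusted over the list alone, adjusted p = 0.0254 with an estimated correlation). The count of 10 became 5 or 3 genes without waterlogging replicate 2 or 3, 6 or 2 without recovery replicate 1 or 2, 6 with a pseudocount of 0.1, and 0 in a limma fit of only the groups compared.

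After submergence, a partner protein of the nitrate transporter NRT2 (OS02G0595900) rose in 35S TRAP RNA from 4.91 ± 2.82 to 336.9 ± 92.4 TPM, the gene BCH2 (OS02G0112600) by 5.80 and the physical impedance induced protein OS03G0103200 by 5.67, while the class III chitinase OS11G0701500 fell from 204.6 ± 80.4 to 5.44 ± 2.09 TPM. In RSS1 a nitrate reductase (OS02G0770800) rose from 2.30 ± 1.43 to 79.4 ± 19.9 TPM and expansin-B7 (OS03G0102700) from 13.9 ± 10.8 to 248.2 ± 25.8, and DIN1 fell from 1303 ± 703 to 32.5 ± 5.58. Of 160 cytosolic ribosomal proteins 137 rose and 3 fell in RSS1 (median 1.71, adjusted p = 4.71e-39) and 26 rose and 1 fell in 35S TRAP RNA (median 0.75, adjusted p = 5.65e-17), at 0.0814 and 0.437 with an estimated correlation. In RSS1 48 of 77 genes of DNA replication and histones rose, and 13 of the mitotic cell cycle rose and 1 fell. There 27 of 46 expansins rose and 3 fell, and 4 of the hypoxia regulators fell (median -2.44). With an estimated correlation the adjusted p was 0.0168, 0.0429, 0.0168 and 0.0184 in that order. The photosynthesis list fell in 35S TRAP RNA (9 genes, adjusted p = 0.00483, and 0.759 with an estimated correlation). Called genes numbered 4288 (2203 higher, 2085 lower) in 35S TRAP RNA and 8077 (4377 and 3700) in RSS1.

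Roots of the paddy field were lower in iron acquisition than control I roots. Of the 14 genes of iron acquisition, 10 were lower in 35S TRAP RNA (median -1.83, adjusted p = 0.0122 with an estimated correlation). The metallothionein OS12G0570700 stood at 134.8 ± 67 against 9460 ± 4930 TPM (-6.06) and the ACC oxidase OS11G0186900 at 1.36 ± 0.902 against 73.7 ± 15.4. A quinoprotein alcohol dehydrogenase-like gene (OS02G0585700) stood at 114.7 ± 48.1 against 2.60 ± 2.67 TPM, and pyruvate decarboxylase OS05G0469600, a fermentation enzyme, at 131.5 ± 124 against 3.63 ± 0.802. In all 735 genes were higher and 1265 lower, and 729 were called in a fit of only the groups compared. Plants in the field were older, so age and site were not separated. Plate roots came from younger seedlings grown on sucrose medium in light. Their photosynthesis transcripts summed to 15140 ± 7800 TPM in 35S TRAP RNA, but to 1234 ± 472 in TOTAL RNA and 233.6 to 996.4 in the other lines. In 35S TRAP RNA, compared with control I, the rubisco small subunit OS12G0291100 stood at 1234 ± 676 against 1.12 ± 0.694 TPM (9.02), and 38 of 44 genes of the photosynthesis list were higher and 1 lower (median 5.71, adjusted p = 0.0115 with an estimated correlation). The metallothioneins OS12G0571000 and OS12G0571100 were lower by log2 values of -8.52 and -6.91. The list of expansins was higher (15 of 38, with 2 lower, adjusted p = 0.00116) and LEA and dehydrins lower (11 of 27, adjusted p = 0.000144), both 0.248 with an estimated correlation, with 3014 genes higher and 2361 lower in all.

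TRAP and TOTAL RNA of the 35S line differed beyond the tag. RPL18 was higher in TRAP RNA by 5.34, an ACC oxidase-like gene (OS02G0771600) stood at 444.3 ± 96.1 against 27.7 ± 9.09 TPM and an epsin-like gene (OS06G0175500), which ranked first in 111 libraries, was higher by 3.92. A Bowman-Birk proteinase inhibitor (OS01G0127600) stood at 10.5 ± 4.35 against 504.1 ± 86.4 TPM, RCc3 (OS04G0554500) at 8.41 ± 2.64 against 371.2 ± 82.9, and the wall enzyme XET2 (OS11G0539200) was lower by a log2 value of -5.23. Lower in TRAP RNA were 86 of the 160 cytosolic ribosomal proteins with 1 higher (median -1.04, adjusted p = 8.12e-38). So were 34 of 77 DNA replication and histone genes, 11 of 25 mitotic cell cycle genes and 22 of 44 expansins with 3 higher. With an estimated correlation the adjusted p was 0.0725, 0.00478, 0.0191 and 0.00801 in that order. In all 3533 genes were higher and 2544 lower, and 2353 higher and 3356 lower after rescaling, which moved the median of all genes from 0.24 to 0.05.

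The stress responses differed between TRAP and TOTAL RNA for 1298 genes under deficit, 21 under waterlogging and 2763 under submergence. Under deficit the response of RCc3 (OS04G0554500) was more positive in TRAP RNA by 4.51 and that of RCc2 (OS10G0551800) by 4.09, and that of embryonic abundant protein 1 (OS05G0349800) more negative (-4.10). Genes of DNA replication and histones (15 more positive, 23 adjusted over the list alone, median 0.65), of the mitotic cell cycle (5) and expansins (15) fell less in TRAP RNA, at adjusted p of 0.00512, 0.0341 and 0.00512 with an estimated correlation. Under submergence the same held for DNA replication and histones (36, median 1.02), the mitotic cell cycle (14 with 1 more negative) and expansins (23). It also held for cytosolic ribosomal proteins (95, median 1.18, adjusted p = 2.44e-37). With an estimated correlation the adjusted p was 0.00215, 0.0136, 0.00131 and 0.0755 in that order. RCc3 and many genes of these lists were already lower in TRAP than in TOTAL RNA of control I, which limits their fall in TRAP RNA. RPL18 in TRAP RNA fell from 52520 ± 53200 TPM in control I to 1655 ± 340 under deficit and from 19290 ± 8100 in control II to 3417 ± 556 under submergence, and a change in tag enrichment was not separated from these differences. A peroxidase (OS05G0499300) differed by 5.51 and RicMT by -3.19, a call lost with a pseudocount of 0.1. Under waterlogging the ACC oxidase OS11G0186900 responded more negatively in TRAP RNA (-2.37, adjusted p = 0.0144) and GST19 (OS07G0468100) more positively (2.62, adjusted p = 0.000513). The call of phenylalanine ammonia-lyase (-4.13, adjusted p = 0.0429) was lost with the replicate number as a block, with a pseudocount of 0.1 and after rescaling. The deficit count held 812 genes more positive and 486 more negative, 1230 and 282 after rescaling, which moved the median of all genes from -0.16 to -0.01, and 862 in a fit of only the groups compared. The waterlogging count held 10 and 11, and 15 and 8 after rescaling, which moved the median from -0.18 to -0.0042. It was 11 genes without TOTAL control I replicate 3 or TRAP control I replicate 1 and 10 without TRAP waterlogging replicate 2, 9 with a pseudocount of 0.1 and 7 in a fit of only the groups compared, and chance was not excluded for it.

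Lines differed from 35S TRAP RNA in 14638 genes in control I, 10104 in the field and 16876 on plates. QHB TRAP RNA was richest in a xylem cysteine proteinase (OS05G0108600), the 1 gene of the phloem and xylem markers list, at 5705 ± 562 against 9.72 ± 3.2 TPM in control I, 5841 ± 3290 against 17.2 ± 1.2 in the field and 3430 ± 59.1 against 25.2 ± 6.97 on plates. All 3 genes of secondary wall cellulose were higher in QHB in the field (median 2.76, adjusted p = 0.0333 with an estimated correlation) and in control I (adjusted p = 0.000393, and 0.159 with an estimated correlation). RSS1 TRAP RNA was richer in RCc3 (OS04G0554500), at 979.3 ± 180 against 8.41 ± 2.64 TPM, and in XET2, at 443.6 ± 111 against 3.39 ± 1.96. Both genes were also far lower in 35S TRAP than in TOTAL RNA, so the excess over TOTAL RNA is smaller. LSI1 TRAP RNA was richer in pyruvate decarboxylases (OS05G0469600, 386 ± 224 against 3.63 ± 0.802 TPM, and OS05G0469800, 723.4 ± 221 against 14.1 ± 6.68), the aquaporin OS02G0823100 (55380 ± 32700 against 802.1 ± 192) and, in the field, the silicon efflux transporter OS03G0107300 (5727 ± 5110 against 33.4 ± 12.7). The CASP, CMZ and SCR lines shared their leading genes in control I. A GDP dissociation inhibitor (OS07G0271000) stood at 2387 ± 210, 2428 ± 1560 and 3607 ± 1310 TPM against 33.9 ± 6.77 in 35S TRAP RNA, and among these 3 lines 7 genes differed, against 10265 among RSS1, QHB and LSI1. The same inhibitor led EXP5B (6.83), HMA5 (5.87) and SHR1 (6.50) in the field. NRAMP5 was richest in an oxophytodienoate reductase (OS06G0215900, 4.82), an enzyme of the jasmonate family, and on plates CMZ, SCR and SHR1 shared an LG27/30-like gene (OS11G0134100) at 7.76, 7.73 and 7.59.

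In control I genes of the mitotic cell cycle were higher than in 35S TRAP RNA in RSS1 (16 of 25), QHB (18), CMZ (17), CASP (18) and SCR (17). With an estimated correlation the adjusted p was 0.00148, 0.00928, 0.0101, 0.0161 and 0.0215 in that order. The list summed to 134 TPM in 35S TRAP RNA, 300 in TOTAL RNA and 486.6 to 537.4 in these lines. The list of expansins was higher in RSS1 (27 of 45, median 2.23, adjusted p = 9.06e-05 with an estimated correlation). LSI1 was lower in pathogenesis-related genes (26 of 78, 33 adjusted over the list alone, with 3 higher, adjusted p = 0.00581 with an estimated correlation) and, with QHB, in nitrate, ammonium and phosphate transporters (11 and 10 of 28, adjusted p = 0.0282 and 0.0391 with an estimated correlation). Genes of suberin and Casparian strip synthesis were higher in LSI1 (5 of 11, with 1 lower, median 1.1, adjusted p = 0.00398, and 0.251 with an estimated correlation). On plates, cytosolic ribosomal proteins were higher in QHB (118 of 160, with 2 lower) and RSS1 (116, with 1 lower), at adjusted p of 0.0301 and 0.00218 with an estimated correlation. There the photosynthesis list was lower than in 35S TRAP RNA in QHB (38 of 44), RSS1 (37) and CMZ (37, with 1 higher, adjusted p = 0.0492 with an estimated correlation). Genes for root hair growth were higher in SHR1 on plates (5 of 8, median 1.2, adjusted p = 0.046, 0.115 with an estimated correlation and 0.0693 after rescaling). The 7 genes of strigolactone synthesis passed the test as a list in no comparison, with a lowest adjusted p of 0.0817 under waterlogging in RSS1, where 1 was higher.

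Chromatin upstream of 2 dehydrin genes opened under deficit. ATAC-seq measures how open chromatin is, here as reads in each gene's upstream region. In 35S nuclei the region of RAB16B rose from 19.8 ± 2.68 to 79.5 ± 20.1 CPM (log2 2.04, edgeR adjusted p = 9.98e-08) and that of RAB16D from 13.3 ± 2.03 to 46.4 ± 15.2 (1.79, adjusted p = 4.26e-06), while that of the metal transport protein OS03G0667300 fell from 68.6 ± 5.18 to 28.1 ± 2.74 (-1.29, adjusted p = 0.0016). Regions of genes that rose in 35S TRAP RNA shifted up as a set (median 0.24, camera adjusted p = 0.00018 with an estimated correlation) and those of genes that fell shifted down (-0.14, adjusted p = 0.00652 with an estimated correlation). Under submergence the regions of DIN1 (34.2 ± 13.7 to 126.5 ± 31.7 CPM), the class III chitinase OS11G0701500 (2.14), a lysine decarboxylase-like gene (OS03G0109300, 2.15) and a bZIP factor (OS03G0796900, 1.97) rose, and those of a glycosyl transferase of family 43 (OS05G0123100, -1.72) and an annexin (OS05G0382600, -1.54) fell. The sets of TRAP genes moved with them, by medians of 0.31 and -0.31 (adjusted p = 0.00012 and 2.9e-05 with an estimated correlation). In CMZ nuclei under deficit a thaumatin-like gene (OS12G0628600) rose by 2.04 and a GAMYB-binding protein (OS10G0408700) fell by 1.82. Regions of genes lower in CMZ TRAP RNA shifted down (-0.22, adjusted p = 0.0398 with an estimated correlation), and those of higher genes did not pass the test (0.07, adjusted p = 0.255). Under deficit 900 strong regions, chosen by their level in 35S control II, had a median of -1.07 in CMZ and -0.316 in 35S, and the shifts down of the TRAP sets in both lines were not separated from this. In QHB nuclei the region upstream of QHB, with any reads of the transgene promoter included, stood at 199.7 ± 94.7 against 26.4 ± 6.69 CPM in 35S (2.92, adjusted p = 0.00115), beside that of a voltage-dependent anion channel (OS01G0715500, 1.42). CMZ differed from 35S in a ribosomal protein S7 gene (OS12G0524750, 6.91) and a DIN1-like gene (OS04G0249600, -1.72).

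Under deficit edgeR called 282 regions in 35S nuclei, 180 higher and 102 lower. Without control I replicate 1 or 3 it called 138 (102 higher, 36 lower) or 89 (70 and 19). Without deficit replicate 3 it called 158, and the majority turned, with 49 higher and 109 lower. It also turned in DESeq2, which called 521, 207 higher and 314 lower. Under submergence edgeR called 2370 regions, 1039 higher and 1331 lower. Without control II replicate 2 or 3 it called 1429 or 1490, without submergence replicate 1 or 2 it called 1245 or 1396, in a fit of only the groups compared 4070, and against control I 7953, of which 4635 were higher and 3318 lower. In CMZ under deficit edgeR called 9 regions, 1 higher and 8 lower, with 51 without control I replicate 1, 1 without deficit replicate 2, 1889 in a fit of only the groups compared and 1571 by DESeq2. In QHB under deficit it called 0 regions, with 3145 at an unadjusted p under 0.05, 1 without deficit replicate 2 and 669 without control I replicate 1, and DESeq2 called 2. Under waterlogging edgeR called 0 regions in 35S, with 2052 at an unadjusted p under 0.05, and 0 in CMZ, with 1222, and DESeq2 called 0 in both. The TRAP gene sets did not pass the test there (35S adjusted p = 0.606 and 0.157, CMZ 0.282 and 0.157). The 2 regions that differed between CMZ and 35S in control I became 1 without 35S replicate 1 or CMZ replicate 2 or 3 and 5 without CMZ replicate 1, and were 20 by DESeq2. The 2 that differed between QHB and 35S became 0 in edgeR without any 1 of the 35S replicates, where the unadjusted count with all libraries was 1364, and 1 without QHB replicate 2 or 3.

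Deficit and submergence, tested against separate controls, shared more falls than rises in 35S TRAP RNA. Both lowered 670 genes, against 223 for independent lists (odds ratio 4.85, Fisher's exact test, adjusted p = 2.28e-172), and both raised 240, against 158.3 (1.67, adjusted p = 8.46e-11). Opposite calls were also above independence, at 222 genes against 160.5 (odds ratio 1.49) and 298 against 219.9 (1.46). The 1.67 of shared rises lies close to these, so it sets no common rise apart. Both responses shared 1 estimate of the spread, and the test takes genes as independent. Of the 39 genes lower under waterlogging, 18 were lower under submergence, against 3.95 (adjusted p = 2.25e-08), and 11 were higher, against 3.89 (adjusted p = 0.00175).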

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

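Of the tests below, those for the similarity of the CASP, CMZ and SCR lines, for the flat CMZ ATAC profile, for green tissue in replicate 3 and for every split or regrouping of the libraries were chosen after the result was seen. Those for a single gene and for separate handling of replicate 3 were set before it was seen.

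Differences between groups in the size of a stress response drew attention in 6 tests. TRAP and TOTAL RNA of 35S differed in response for 1298 genes under deficit, 21 under waterlogging and 2763 under submergence, and lines differed for 1446, 21 and 3663. The mean of each line or pool was first removed, and line or pool labels were then regrouped at random within each environment, in 100 draws that included the real one. As many genes were called in 1 of 100 for TRAP by deficit (highest other 746), 7 for TRAP by waterlogging (186), 1 for TRAP by submergence (1098), 1 for deficit by line (5), 2 for waterlogging by line (67) and 1 for submergence by line (3). Under this scheme chance was excluded, at a share under 0.05, for all of these but TRAP by waterlogging, where other draws called up to 186 genes against the real 21. Regrouping the environment labels within each line or pool gave other shares, at 15, 21, 18, 5, 3 and 7 of 100 in the same order, with highest others of 9807, 398, 10326, 2534, 26 and 7489. Under that scheme chance was excluded only for waterlogging by line. That share and the share of deficit by line lie close to 0.05, and in another set of draws each fell on the other side of it, so neither settles the question. For TRAP by waterlogging same-numbered libraries were correlated (0.137 to 0.62), a structure that both schemes break, so the draws do not settle that count. The schemes thus differ for TRAP by deficit, TRAP by submergence, deficit by line and submergence by line. The first scheme was adopted after the counts of the second were seen, on the ground that regrouped environments carry the shared stress effect into the interaction.

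For comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. In each of the RNA comparisons the real split alone, 1 of 10, gave as many genes. For deficit the real counts were 5690 in TOTAL RNA, 3790 in 35S TRAP RNA, 3977 in RSS1, 2178 in CMZ, 1882 in SCR, 1153 in CASP, 3852 in LSI1 and 3506 in QHB, and the highest others were 11, 0, 2, 0, 0, 0, 0 and 0. For waterlogging they were 222, 45, 139, 14, 1, 7 and 403 in TOTAL, 35S, RSS1, CMZ, SCR, CASP and LSI1, with highest others of 0, 3, 0, 1, 0, 0 and 1. For submergence they were 9510, 5289 and 10495 in TOTAL, 35S and RSS1, with 1, 0 and 24. For recovery they were 3671 after deficit, 10 after waterlogging, and 4288 and 8077 after submergence in 35S and RSS1, with 61, 8, 2 and 48. Field against control I gave 2000 with 390, plates 5375 with 0, and TRAP against TOTAL RNA 6077 with 47. In the ATAC data deficit gave 282 in 35S with 0 and 9 in CMZ with 0, submergence 2370 with 1, and CMZ or QHB against 35S 2 with 1. The edgeR counts of 0 regions, in QHB under deficit and in 35S and CMZ under waterlogging, were reached by 10 of 10 splits, with highest others of 7, 0 and 1. Where numbers pair the libraries, splits that part as many pairs as the real one gave at most 0 genes by limma. Among all lines, 1 of 100 regroupings gave as many genes as the real 14638 in control I (highest other 1094), 10104 in the field (468) and 16876 on plates (10942), which excludes chance.

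In plate-grown CMZ roots, the only group of 4 libraries, 1 library lay far from the others in summed TPM of the mitotic cell cycle list, at 520.2 against 416.9, 420.3 and 426.3 (gap over range 0.909). This was 1 of 21 lists tested, and chance gives about 1 in 20. Signals above control I also stood in groups that entered no comparison. Photosynthesis transcripts summed to 1234 ± 472 TPM in TOTAL RNA of plate roots against 114.3 ± 68.5, LEA and dehydrins to 1887 ± 497 in TOTAL RNA after waterlogging recovery against 936.6 ± 83.0, and anaerobic fermentation to 21980 ± 5850 in LSI1 after deficit recovery against 10260 ± 1630.

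The CASP, CMZ and SCR lines lay near one another in control I. Their 7 genes called among themselves were 0.0682% of the 10265 called among RSS1, QHB and LSI1, and little RNA from tagged ribosomes, with untagged root RNA as a large part, may explain this. The highest ratio of mean RPL18 TPM to TOTAL RNA in these lines was 1.47, against 18.6 in RSS1 and 51.9 in LSI1. Little tag transcript would give a low ratio, but that TOTAL RNA is of the tagged 35S line and no level without the tag. The SCARECROW genes, both under 10 TPM, cannot tell apart enrichment for different domains (highest difference from 35S 0.573). Overlapping cells under the 3 promoters would give few differences too, were not tested and stay open.

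Photosynthesis transcripts were high in replicate 3 of many CASP, CMZ and SCR groups, and 10 of the 12 greenhouse and field libraries above 1000 summed TPM were of this kind. Plate libraries were left out of this count, since plate roots held many such transcripts in 35S. A single gene held 16.8% of the excess, which argues against one gene taking the sum. RNA from green tissue might add such transcripts, but the median share of photosynthesis genes higher in replicate 3, 77.3%, fell short of the 80% set for it, so it cannot be told apart. Separate handling of these replicates cannot be told apart either, as the median correlation of replicate 3 deviations between lines, outside the list, was 0.157. The design gives no biological explanation, and none was tested.

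CMZ ATAC libraries under deficit had a flatter profile than in control I. With every library thinned to 1134866 counts, the share of the 100 strongest regions was 0.42 times that of control I, which argues against depth. The 900 regions ranked next in 35S control II had a median log2 fold change of -1.07 in CMZ, a size that a smaller share of reads from open regions could give. A loss of open chromatin in every line under deficit cannot be told apart, with medians of -0.316 in 35S and -0.95 in QHB. A change of chromatin in CMZ cells themselves under deficit was not tested and stays open.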

How the results depend on the processing

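The fit without greenhouse and field libraries above 1000 summed TPM of photosynthesis genes was the 1 alternative chosen after the data were seen. For each change below the cause was not tested, except that leaving out libraries leaves fewer samples. The depth behind the TPM is unknown, so no limit of detection can be given for RNA, and the ATAC libraries of 812498 to 17113727 counts recovered few regions changed 1.5-fold in simulation. The 34 RNA counts stayed within 1.5 times without the filter on low values, and the 8 ATAC counts without their filter and with the size factors of DESeq2 in edgeR. Rescaling kept 31 of the 34, a pseudocount of 0.1 kept 32, the replicate block 35 of 42 and a fit of only the groups compared 22 of 36. No list or named gene that was called changed its sign under the alternatives run for it. The majority among called genes or regions did turn in some comparisons. TRAP against TOTAL RNA went from more genes higher to 2353 higher and 3356 lower after rescaling, and ATAC deficit in 35S went from more regions higher to 207 higher and 314 lower by DESeq2 and 49 and 109 without deficit replicate 3. ATAC submergence went from more regions lower to 4635 higher and 3318 lower with control I, and waterlogging in LSI1 from near even to 672 and 311 in a fit of only the groups compared. Submergence in TOTAL RNA turned to more genes higher with control I, and near-even splits, such as those of deficit in CASP, LSI1 and QHB and of submergence in RSS1, turned with 1 or more alternatives. Of 404 lists called, 302 lost the call with an estimated correlation, 17 after rescaling, 12 with a pseudocount of 0.1 and 10 with the replicate block. Of 388 gene calls named by the rule, 6, 18 and 5 were lost with the last 3.

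In a fit of only the groups compared, waterlogging gave 111 genes in TOTAL RNA, 3 in 35S TRAP RNA, 63 in RSS1, 6 in CMZ, 983 in LSI1 and 0 in SCR and CASP by limma. Waterlogging recovery gave 0 and the field 729, and the TRAP interactions 862 under deficit and 7 under waterlogging. ATAC regions numbered 1889 in CMZ under deficit, 4070 under submergence and 1 between QHB and 35S. With the replicate block, waterlogging gave 25 genes in CMZ, 8 in SCR and 23 in CASP, the line interactions 2315 under deficit and 118 under waterlogging, and the ATAC data 45 regions in CMZ under deficit and 8 between CMZ and 35S. Among comparisons whose numbers pair the libraries, the count of CASP was the 1 that the block moved, and these counts were seen before the pairing was examined. After rescaling, waterlogging gave 0 genes in SCR by limma and 4 in CASP, and its line interaction 32. With a pseudocount of 0.1, waterlogging recovery gave 6 and the TRAP by waterlogging interaction 9. With control I in place of control II, the submergence by line interaction gave 2113 genes and ATAC submergence 7953 regions, of which 58.3% were higher. DESeq2 called 521 regions in 35S, 1571 in CMZ and 2 in QHB under deficit and 20 between CMZ and 35S. Without the libraries rich in photosynthesis transcripts, waterlogging gave 70 genes in RSS1 and 13 in SCR, and 9 other counts stayed within 1.5 times. With the 500 genes of smallest p, regions of genes higher in 35S TRAP RNA under waterlogging reached an adjusted p of 0.0413, over a range of 0.0413 to 0.662.

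With each replicate left out in turn, 301 of 388 counts stayed within 1.5 times. The others, lowest to highest, were 998 to 1690 genes in SCR and 753 to 1045 in CASP under deficit. Under waterlogging they were 126 to 249 in TOTAL RNA, 16 to 37 in 35S TRAP RNA, 59 to 102 in RSS1, 2 to 21 in CMZ, 0 to 12 in SCR, 2 to 8 in CASP and 105 to 153 in LSI1. Waterlogging recovery gave 2 to 11, the TRAP by waterlogging interaction 10 to 21, and the line interactions 941 to 1752 under deficit, 2 to 71 under waterlogging and 1944 to 5315 under submergence. ATAC deficit gave 89 to 306 regions in 35S, 1 to 51 in CMZ and 0 to 669 in QHB, ATAC submergence 1245 to 2268, CMZ against 35S 1 to 5 and QHB against 35S 0 to 2.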
